A study of Mus musculus with 8 samples.

How the data were processed

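RNA sequencing of 8 mouse heart samples was used, with 4 from animals given an adeno-associated virus carrying mouse Fgf17 and 4 from animals given its control vector. Total RNA was extracted with Trizol and sequenced on Illumina libraries, per the labels' protocols. The submitters' processing notes name FastQC 0.11.7, cutadapt 1.17, HISAT2 2.1.0 and StringTie 1.3.3 and the GRCm38 mouse genome, with no order and no settings. The deposited values are FPKM, fragments scaled by transcript length and by the mapped fragments of the library, 1 value per gene and library, per the file headers. The table lists 11704 genes, all protein-coding, and 1 empty line, which was left out. In every listed gene the larger of the group means was at least 0.501 FPKM, so genes below that level in both groups were not analysed here. FPKM divides by the total of each library, so a library with fewer mitochondrial transcripts has higher values for its nuclear genes. StringTie estimates a gene's value from the transcripts it assembles, and reads of the vector's Fgf17 and of the endogenous gene enter the same value.

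No read counts were used here and the sequencing depth of the libraries is unknown. To look for it, the low values of 1143 genes with a single annotated transcript were searched for whole-read steps, and in 0 of the 8 libraries did the step score exceed that of jittered values by over 0.05. Tests made for counts were therefore not run, and the precision of each value is given by the spread between hearts. The median gene had a 95% confidence half-width of 0.334 for its log2 change.

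Columns were assigned to samples by matching their names to the sample titles, and 0 columns of per-sample values were left unassigned. The columns are named for sham and the series title mentions a sham operation and infarction, while the sample labels describe transduction only, so whether these hearts were operated on is unknown. The labels number the hearts 1 to 4 in each group. They do not say that the samples are separate animals in so many words, so p-values measure the spread between these samples. Genes with a mean of at least 1 FPKM over the 8 libraries were tested, which left 10025. Values were transformed to log2(FPKM + 1), and a fold change on that scale understates the change of low genes. The groups were compared with limma 3.58.1 in R 4.3.3, with a variance trend on the mean, no covariates and Benjamini-Hochberg adjustment at 0.05. The median of all tested genes lay at -0.12 on the log2 scale as deposited and at -0.00 after median-of-ratios scaling. Log2 changes of genes and lists are therefore given relative to the median gene, except where the text says as fitted. The p-values of limma, over all genes or over a list alone, and of fry test the change as fitted against 0. Single values, such as the per-library score of a list, were compared with a two-sided exact permutation test, whose smallest p with 4 against 4 is 0.0286. Principal components were taken over the centred log2 values of the tested genes.

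Before the data were examined, 37 pathway lists and 22 cell-type marker lists were fixed, along with the tests, the alternatives and the rule for naming genes. Lists with at least 3 tested members were compared with the other genes by limma's camera with a preset inter-gene correlation of 0.01, and 6 of the 59 lists were too small. The same lists were run with an estimated correlation and with limma's fry, which asks whether the genes of a list move on balance in 1 direction. The score of a list in a library is the mean of its members' log2 values, each centred on its mean over the 8 libraries. The library's median of these centred values over all tested genes was subtracted first. The rule named Fgf17, then up to 10 genes in each direction past the threshold with no overlap of the groups. Where fewer than 5 passed, it named the genes of smallest p up to 5, predicted gene models left out. It also named the 4 members of smallest p in each pathway list described and the 2 most abundant members of each cell-type list, of which 1 gene is not reported here.

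Coordinates, gene lengths, GC content and transcript numbers came from the GENCODE M21 annotation of GRCm38, which holds 11698 of the 11704 genes (99.95%). The coordinates of the files equal those of that annotation for 10728 genes. The fit and camera were tested on simulated data drawn from the real means and spreads of the 10025 genes. In these, 200 genes were changed 2-fold or 4-fold on the log2(FPKM + 1) scale, which for low genes is a larger change in FPKM. A further list of genes got a smaller shift to test camera. Calls of that list are in the totals of calls below but count neither as changed nor as false. With the libraries' own unequal spreads, 75% of genes changed 2-fold and 97% of genes changed 4-fold were called, with 2 false calls among 181. With equal spreads these shares were 81% and 92%, with 13 false calls among 200. Noise was drawn for each gene independently, in 1 run per setting. The simulation thus lacks the correlation between genes of the real data, so its rates need not hold for them. Per-library checks used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

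The alternatives were pseudocounts of 0.1 and 0.01, no filter, minimum means of 0.1 and 5 FPKM, median-of-ratios scaling, quantile normalization, a robust variance model, array quality weights, the replicate number as a block, and each library left out in turn. After the data were seen, 4 were added. They left out control libraries 2 and 3, counted control libraries 1 and 4 as 1 sample, did both, or rescaled each library on its sum without mitochondrially encoded genes.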

Results

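Gene expression was measured by RNA sequencing in 8 mouse heart samples. Newborn animals had received, under the skin, an adeno-associated virus of serotype 9, a vector that transduces heart muscle. For 4 samples the virus carried Fgf17, which encodes a secreted fibroblast growth factor of the FGF8 subfamily, and for 4 it was the control vector. Hearts were collected at 8 to 10 weeks of age. Values are FPKM, and the number of reads behind them is unknown. The comparison asks how the transcriptome of the adult heart differs when Fgf17 is supplied by the vector.

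Fgf17 itself (ENSMUSG00000022101.6, chromosome 14, 70636203 to 70642268 on the minus strand of GRCm38) was present at 114 ± 45.3 FPKM (SD, n = 4) in AAV-FGF17 hearts and at 5.36 ± 5.05 FPKM (n = 4) in control hearts. The AAV-FGF17 hearts measured 90.8, 173, 69.0 and 123 FPKM, and the lowest of them lay 7-fold above the highest control. The control hearts measured 9.59, 1.43, 0.560 and 9.86 FPKM. The groups did not overlap (two-sided exact permutation p = 0.0286, the smallest possible with 4 against 4). The log2 change as fitted was 4.57 ± 0.61 (SE; 95% interval 3.20 to 5.94), and its limma adjusted p over all genes was 0.248. Fgf17 passed the limma threshold without control library 1 (adjusted p = 0.0369), without control libraries 2 and 3 (0.0353) and with array quality weights (0.0189). Over all alternatives its adjusted p ran from 0.0189 to 0.725. Without control libraries 2 and 3 its log2 change as fitted was 3.34, and stayed so with control libraries 1 and 4 counted as 1 sample. That leaves 1 control sample, so no test is given for it.

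**Figure D1:**
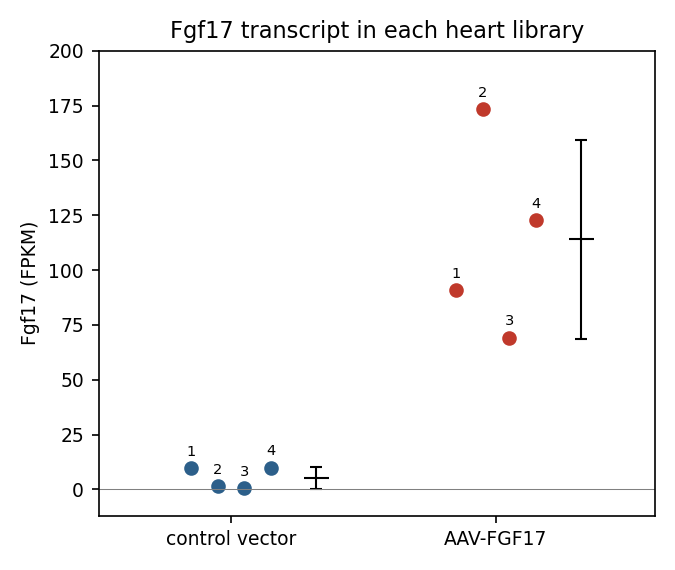
Fgf17 abundance in FPKM (vertical axis) in each control vector and AAV-FGF17 library (horizontal axis). Points are libraries with their replicate number, and bars give the mean and SD of 4 libraries. The AAV-FGF17 libraries lie between 69.0 and 173 FPKM and the controls between 0.560 and 9.86 FPKM.

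No gene passed the threshold in either direction. With limma, 0 of 10025 genes were higher and 0 lower at an adjusted p of 0.05, and the smallest adjusted p, 0.248, was that of Fgf17. At an unadjusted p under 0.05 there were 936 genes, against 501 by chance, of which 136 were higher and 800 lower in AAV-FGF17 hearts. After median-of-ratios scaling the split was 429 higher and 407 lower. Without control libraries 2 and 3, which stood apart from the rest, 5 genes were higher and 1 lower. Those calls rest on control libraries 1 and 4, the most similar pair, counted as 2 samples. Array quality weights gave 4 higher and 1 lower. All 4 AAV-FGF17 hearts lay above all 4 controls in 100 genes and below them in 465, together 5.64% of genes, against 2.86% by chance.

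The genes of smallest p after Fgf17 missed the threshold and are given as values. Ackr4, an atypical receptor that scavenges chemokines, stood at 3.20 ± 0.540 FPKM in AAV-FGF17 hearts and 1.24 ± 0.280 in controls. Its log2 change as fitted was 0.91 ± 0.14 (SE, limma adjusted p = 0.319). Tmem168, a membrane protein gene, stood at 4.07 ± 0.209 against 1.64 ± 0.792 FPKM (adjusted p = 0.495 by limma). Ms4a4d measured 22.8 ± 2.03 against 11.8 ± 3.72 FPKM, and Agtr1a, the angiotensin II type 1a receptor, 6.79 ± 0.609 against 4.37 ± 0.474 FPKM. On the lower side Gpc3, the heparan sulphate proteoglycan glypican 3, stood at 4.45 ± 0.581 FPKM against 11.8 ± 3.62. Its log2 change as fitted was -1.20 ± 0.19 (SE, limma adjusted p = 0.348). Eln, elastin, measured 3.89 ± 0.471 against 6.58 ± 0.329 FPKM, and Timp4, an inhibitor of matrix metalloproteinases, 2.94 ± 0.367 against 4.94 ± 0.449 FPKM. Eme2, a subunit of a structure-specific endonuclease, measured 0.413 ± 0.191 against 1.71 ± 0.547 FPKM. Fyttd1, an mRNA export factor, measured 4.507 ± 0.1001 against 9.53 ± 2.64 FPKM. All of these separated the groups in 4 of 4 hearts, and limma adjusted p-values lay between 0.319 and 0.495.

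Genes of the FGF family, its receptors and cofactors, and its target genes were read through 3 fixed lists. Of the 15 tested members of the ERK feedback and FGF target list, 10 lay above the median gene and 5 below it, with a list median of 0.15 relative to the median gene (camera adjusted p = 0.0628). None passed limma, whether over all genes or adjusted over the list alone. Spry1, a feedback inhibitor of receptor tyrosine kinase signalling, stood at 9.92 ± 1.27 FPKM in AAV-FGF17 hearts and 5.71 ± 2.11 in controls, higher in 4 of 4 hearts. Its log2 change as fitted was 0.76 ± 0.23 (SE, limma adjusted p = 0.495), against 0.39 without control libraries 2 and 3. Dusp5, a phosphatase of ERK, measured 0.976 ± 0.318 against 1.38 ± 0.299 FPKM. Epha2 measured 0.9705 ± 0.224 against 1.29 ± 0.299 FPKM, and Phlda1 7.83 ± 1.16 against 9.26 ± 1.21 FPKM. Leaving out AAV-FGF17 library 1 or 3 brought the list past the threshold, but over all alternatives the adjusted p ran from 0.0128 to 0.974, with 0.540 without control libraries 2 and 3.

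The list named FGF ligands holds FGF family genes other than Fgf17. Its 9 tested members include Fgf13, at 8.53 ± 1.503 FPKM against 6.18 ± 2.12, and Fgf16, at 8.02 ± 1.204 against 6.98 ± 0.651. The log2 change of Fgf13 as fitted was 0.10 without control libraries 2 and 3, against 0.45 with them. Fgf12 stood at 4.16 ± 3.08 against 5.68 ± 1.89 FPKM and Fgf1 at 37.0 ± 4.29 against 41.0 ± 7.01. The FGF ligand list did not pass (camera adjusted p = 0.113). The 5 tested FGF receptor and cofactor genes had a median of -0.03 relative to the median gene (camera adjusted p = 0.972). Fgfr1 measured 2.98 ± 0.220 against 3.42 ± 0.651 FPKM and Fgfrl1, a receptor without a kinase domain, 1.03 ± 0.265 against 1.56 ± 0.570. Fgfbp3 measured 1.40 ± 0.523 against 1.90 ± 1.68 FPKM and Flrt2 1.18 ± 0.394 against 1.49 ± 1.04.

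Among the 53 lists tested, camera with the preset correlation placed 2 higher and 7 lower in AAV-FGF17 hearts. With an estimated correlation none passed (smallest adjusted p = 0.974), and none passed with fry (smallest adjusted p = 0.319). The estimated inter-gene correlation had a median of 0.303, and it was above 0.01 in 52 lists. No member of any list passed limma over all genes. By the exact permutation test on list scores, with 1 score per library, the smallest adjusted p was 0.433. The unadjusted p of that test was 0.0286 for the mesothelial, brown adipocyte and fetal and hypertrophic lists. It was 0.0571 for smooth muscle, glycolysis and lipid synthesis, and 0.0857 for basement membrane. For white adipocyte it was 0.114, for the mitochondrial list 0.143, and for atrial and erythroid lists 0.171.

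Markers of white adipocytes fell as a list. All 8 tested markers lay below the median gene, with a median of -0.86 relative to it (camera adjusted p = 0.0021; adjusted p = 0.974 with an estimated correlation). Adjusted over the list alone, 6 markers passed limma, namely Adipoq, Pck1, Car3, Cidec, Plin1 and Cfd. Cfd, the adipokine adipsin, stood at 44.7 ± 34.4 FPKM against 110 ± 68.4, and Car3, a carbonic anhydrase abundant in fat, at 36.6 ± 26.1 against 66.6 ± 19.3. AAV-FGF17 library 3, with 95.7 FPKM of Cfd, lay among the controls. Brown adipocyte markers did not pass as a list (camera adjusted p = 0.0828), but did with median-of-ratios scaling (0.0398), and over all alternatives the adjusted p ran from 0.0279 to 0.974. Their 2 markers past limma adjusted over the list alone were Cidea, at 32.5 ± 4.94 against 53.5 ± 13.6 FPKM, and Ucp1, at 5.25 ± 3.39 against 13.6 ± 1.87 FPKM. Cox8b, the most abundant member and also in the list of nuclear-encoded respiratory chain genes, measured 241 ± 27.5 against 271 ± 56.6 FPKM. Without control libraries 2 and 3 the brown adipocyte list had a median change as fitted of -0.20, against -0.47 with them (camera adjusted p = 0.338).

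The lists of atrial, smooth muscle and mesothelial markers fell as well, by camera with the preset correlation. All 12 atrial markers lay below the median gene, with a median of -0.79 relative to it (camera adjusted p = 0.0043; adjusted p = 0.981 with an estimated correlation), and 0 passed limma adjusted over the list alone. Nppa, atrial natriuretic peptide, stood at 950 ± 487 FPKM against 1609 ± 430, and Myl7, the atrial regulatory light chain, at 252 ± 149 against 447 ± 193. Of the 8 smooth muscle markers, 7 lay below the median gene (median -0.48 relative to it; camera adjusted p = 0.0071, or adjusted p = 0.974 with an estimated correlation). Adjusted over the list alone, 6 passed limma, among them Tagln, at 18.0 ± 5.55 against 32.6 ± 9.13 FPKM, and Acta2, smooth muscle actin, at 74.0 ± 18.9 against 106 ± 15.6 FPKM. Of the 7 epicardial and mesothelial markers, 6 lay below the median gene (median -0.27; camera adjusted p = 0.0174, or adjusted p = 0.974 with an estimated correlation). Krt19 and Upk3b passed limma adjusted over the list alone, at 2.91 ± 1.07 against 6.98 ± 2.07 FPKM and at 2.58 ± 1.15 against 4.63 ± 0.693 FPKM. These 4 lists passed camera without control libraries 2 and 3 too, with adjusted p from 8.09e-05 to 0.000213, and each missed it there with an estimated correlation (adjusted p = 0.963). Atrial, smooth muscle and mesothelial lists missed it when control library 1 or 4 was left out, with highest adjusted p-values of 0.0621, 0.0668 and 0.079.

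**Figure D2:**
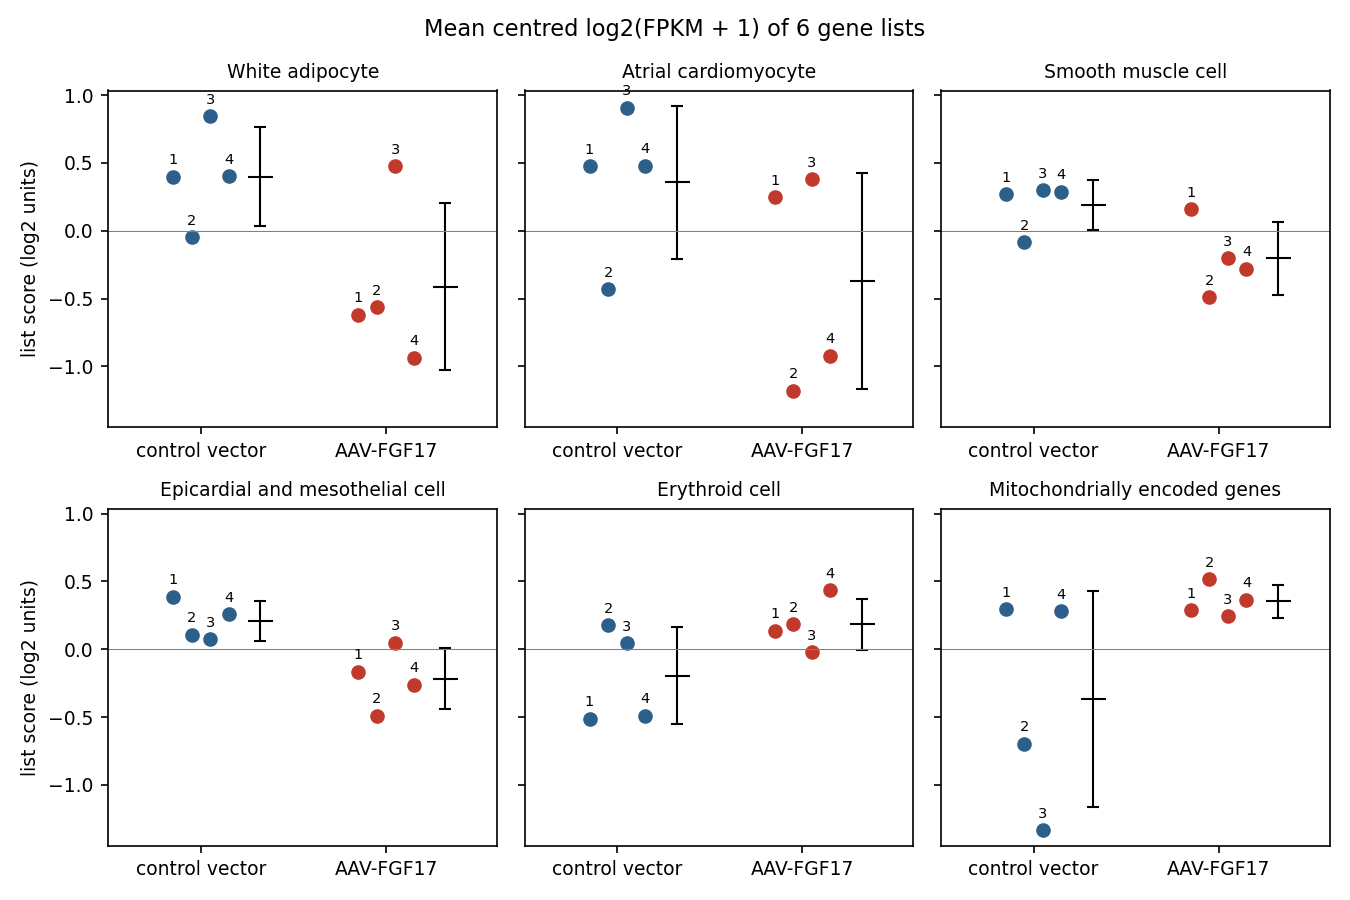
Score of 6 gene lists in each library (vertical axis, log2 units), for control vector and AAV-FGF17 libraries (horizontal axis). The score is the mean over the list of log2(FPKM + 1), centred on each gene's mean and then on the library's median. Points are libraries with their replicate number, and bars give the mean and SD of 4 libraries. Atrial scores of AAV-FGF17 libraries 2 and 4 lie at -1.18 and -0.92, while libraries 1 and 3 lie at 0.25 and 0.38.

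Mitochondrially encoded transcripts rose as a list, with all 13 above the median gene and a median of 0.76 relative to it (camera adjusted p = 5.95e-10; adjusted p = 0.974 with an estimated correlation). This followed 2 control libraries. Mitochondrially encoded genes made up 64.1%, 66.9%, 62.8% and 63.4% of the FPKM sum in AAV-FGF17 libraries 1 to 4, and 64.0%, 44.5%, 30.9% and 64.1% in control libraries 1 to 4. Without control libraries 2 and 3 the camera adjusted p was 0.292. The mt-Nd3 gene of complex I stood at 6309 ± 882 FPKM against 3834 ± 1447, and mt-Co3 of complex IV at 9335 ± 973 against 6817 ± 2041. The ATP synthase genes mt-Atp6 and mt-Atp8 missed the limma threshold too, with log2 changes as fitted of 0.63 ± 0.35 and 0.80 ± 0.42 (SE) and an adjusted p of 0.496.

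Control libraries 2 and 3 also lay apart in nuclear genes. On the first principal component, which held 49.7% of the variance, they scored 22 and 44.6, and the other 6 libraries scored between -19.4 and -7.55. The cardiomyocyte list scored 0.35 and 0.48 in them and between -0.20 and -0.00 in the rest. That list did not pass (camera adjusted p = 0.168, or 0.0442 after rescaling without mitochondrial genes), and Mb, myoglobin, measured 3988 ± 301 against 5279 ± 1755 FPKM, with Fabp3, the heart fatty acid-binding protein, at 3144 ± 338 against 3975 ± 1452. Fgf17 was lower in these 2 control libraries, at 0.874% of the AAV-FGF17 mean, than in control libraries 1 and 4, at 8.53%. Control libraries 1 and 4 were the most similar of the 28 pairs, with a robust SD of 0.0635 for their log2 ratio over 561 abundant nuclear genes. The next pairs crossed the groups: AAV-FGF17 library 3 stood at 0.108 against control library 1 and at 0.108 against control library 4. The lowest pair within the AAV-FGF17 group, libraries 1 and 3, stood at 0.115. Sampling noise cannot be computed from FPKM, so control libraries 1 and 4 were kept as 2 samples.

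**Figure D3:**
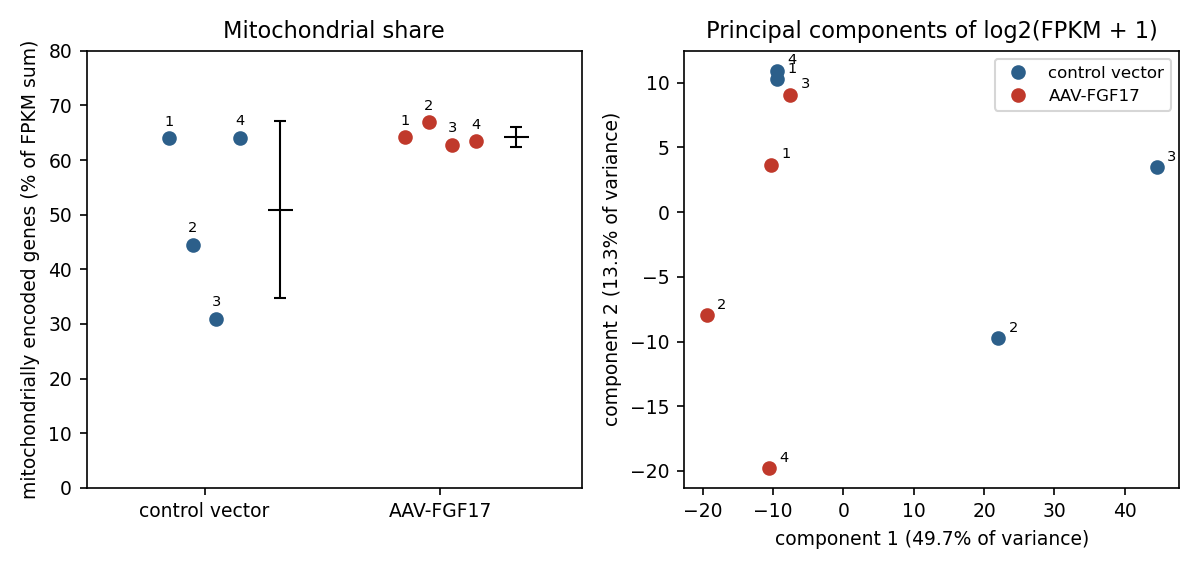
Left, share of the FPKM sum held by mitochondrially encoded genes (vertical axis, percent) in each control vector and AAV-FGF17 library, with the mean and SD of 4 libraries. Right, the first principal components of log2(FPKM + 1), with 49.7% and 13.3% of the variance on the axes; points carry replicate numbers. Control libraries 2 and 3 hold 44.5% and 30.9% and lie at 22 and 44.6 on the first component.

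Glycolysis, basement membrane and lipid synthesis lists fell, and each lost its call without control libraries 2 and 3. Of 26 glycolysis and glucose uptake genes, 24 lay below the median gene (median -0.13; camera adjusted p = 0.0184, or adjusted p = 0.981 with an estimated correlation, and 0.756 without those libraries). Hk1 measured 18.7 ± 2.45 against 26.2 ± 6.95 FPKM, Hk2 60.9 ± 4.14 against 75.5 ± 13.6 and Pfkm 169 ± 11.4 against 249 ± 94.1. Pfkfb3 had a log2 change of -0.66 ± 0.35 (SE). Of 14 basement membrane genes, 12 lay below the median gene (median -0.20; camera adjusted p = 0.0219, or adjusted p = 0.981 with an estimated correlation, and 0.505 without those libraries). Col18a1 stood at 1.48 ± 0.497 FPKM against 4.12 ± 2.13, Agrn at 2.01 ± 0.596 against 3.84 ± 1.39 and Col4a2 at 31.8 ± 6.72 against 52.1 ± 19.8. Of 18 cholesterol and fatty acid synthesis genes, 12 lay below the median gene (median -0.11; camera adjusted p = 0.0425, or adjusted p = 0.981 with an estimated correlation, and 0.229 without those libraries). Scd1, stearoyl-CoA desaturase, and Thrsp, a lipogenic factor, passed limma adjusted over the list alone, at 12.97 ± 7.05 against 27.5 ± 5.79 and 8.41 ± 1.63 against 14.9 ± 4.66 FPKM. Like the adipocyte marker Pck1, Scd1 stood in AAV-FGF17 library 3 (23.5 FPKM) among the controls. Fasn, fatty acid synthase, stood at 1.58 ± 0.738 against 3.64 ± 1.62 FPKM.

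Erythroid genes rose as a list, with all 6 above the median gene and a median of 0.33 relative to it (camera adjusted p = 0.0021; adjusted p = 0.974 with an estimated correlation). Hba-a2, an alpha globin, stood at 314 ± 54.1 FPKM against 239 ± 55.0, and Hbb-bs, a beta globin, at 399 ± 74.0 against 379 ± 171. The globin genes are near-identical copies, so the division of reads among them is uncertain. The list scores were lowest in control libraries 1 and 4, at -0.51 and -0.49. Without either of these the list missed the threshold, with a highest camera adjusted p of 0.0609. Without control libraries 2 and 3 its median change as fitted was 0.70, against 0.21 with them. The camera adjusted p there was 5.74e-12, or 0.781 with an estimated correlation.

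Lists of the heart muscle programme and matrix did not pass. The fetal and hypertrophic list, which holds genes re-expressed in stressed myocardium, had 14 of 20 members below the median gene (median -0.20; camera adjusted p = 0.145), and passed with median-of-ratios scaling (0.0406) and under 4 further settings, with 0.201 without control libraries 2 and 3, 0.406 without AAV-FGF17 library 2 and 0.981 with an estimated correlation. Its members of smallest p were Acta2, Mybphl, Myl4 and Cilp. Mybphl stood at 16.2 ± 10.9 FPKM against 35.5 ± 14.3, Myl4 at 35.5 ± 22.8 against 80.4 ± 47.2 and Cilp at 2.56 ± 1.38 against 4.64 ± 1.87. Mybphl and Myl4 are abundant in atrial muscle. The adult sarcomere and calcium-handling list had 17 of 22 members below the median gene (median -0.25; camera adjusted p = 0.157). This followed control libraries 2 and 3, and without them the list turned to higher, with a median change as fitted of 0.016 (camera adjusted p = 0.292). Atp2a2, the calcium pump of the sarcoplasmic reticulum, measured 866 ± 137 FPKM against 1324 ± 433, and Ryr2, its calcium release channel, 38.8 ± 8.09 against 51.0 ± 8.15. Of 35 fibrillar collagen and matrix genes, 26 lay below the median gene (median -0.21; camera adjusted p = 0.251), and Eln passed limma adjusted over the list alone. The list had a median change as fitted of -0.036 without control libraries 2 and 3 (camera adjusted p = 0.769). Dcn, decorin, stood the other way, at 107 ± 7.75 FPKM against 80.3 ± 12.2, and Lum, lumican, at 32.7 ± 4.02 against 26.1 ± 1.61. The glucocorticoid and fasting response list did not pass (camera adjusted p = 0.113), with Sgk1 at 14.7 ± 2.69 against 10.9 ± 2.33 FPKM and Ddit4 at 22.1 ± 5.79 against 14.98 ± 4.14. Lcn2 and Fkbp5 stood the other way, at 1.51 ± 0.413 against 2.07 ± 0.237 and 6.79 ± 0.772 against 9.51 ± 2.87 FPKM, and without control libraries 2 and 3 the list turned to lower (camera adjusted p = 0.526).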

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

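Each group of 4 libraries was searched for a library far from the other 3, over the library measures, the described lists and the named genes, and the tests of the marker lists, the muscle share and the mitochondrial scale factor below were chosen after the result was seen. The criterion for the atrial score replaced an earlier one when its values were already known. A library stood far from its group in 17 of 228 groups, where chance alone gives about 11.4. AAV-FGF17 library 3 was far above its group in Cfd (95.7 FPKM), Scd1 (23.5) and Pfkfb3 (2.80), and below it in Ms4a4d (19.8). AAV-FGF17 library 4 was above its group in Ackr4 (4.005 FPKM), Cox8b (282) and Acta1 (383), and AAV-FGF17 library 2 was below it in the fetal and hypertrophic score (-0.53). Control library 3 was above its group in Cfd (212 FPKM), Myl4 (151), S100a9 (47.7), S100a8 (29.2) and the fetal and hypertrophic score (0.31). Control library 2 was above its group in Fgf1 (51.4 FPKM) and below it in Dusp5 (0.935), Ddit4 (8.81) and the smooth muscle score (-0.084).

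Control libraries 2 and 3 stood apart from the other 6 in mitochondrial share and in many nuclear genes. A scale factor set by the mitochondrial transcripts would leave no difference once the log2 ratios are centred, yet the centred spread of control library 3 against libraries 1 and 4 was at least 0.486, above the highest of the 15 pairs among the other 6 libraries, 0.220. A smooth trend on GC content and transcript length took up 19.8% of the variance of their difference from control libraries 1 and 4 over 2737 genes. The difference correlated with GC content (Spearman 0.464) and with length (-0.212). Most of the variance lay outside the trend, but it includes noise of unknown size. How much of the systematic difference such a bias makes up is therefore unknown. A larger share of muscle would lower the markers of all other cell types alike, and the medians of 9 such lists lay between -0.28 and 0.63 relative to the median gene, 4 of them below it. A Kruskal-Wallis test between the lists gave p = 0.043 by permutation of the members and 0.0521 by its approximation. It treats the markers of a list as independent, so it cannot decide, and a larger share of muscle stays open. A difference in RNA preparation or between the animals was not analysed here.

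The lists of fat, atrial, smooth muscle and mesothelial markers were lower in AAV-FGF17 hearts by camera with the preset correlation and missed the threshold with an estimated one (adjusted p = 0.974 to 0.981). Without control libraries 2 and 3 the median change as fitted of the 35 markers was -0.71, so the lower values do not depend on those libraries. That value rests on control libraries 1 and 4, the most similar pair, as the only controls. Control library 2 scored below both of them in each of these lists, while control library 3 scored above both in the white adipocyte, atrial and smooth muscle lists. Atrial, smooth muscle and mesothelial lists lost their camera call when control libraries 1 and 4 were counted as 1 sample. An uneven share of atrial tissue between samples may account for the atrial part, since the atrial score ranged over the AAV-FGF17 libraries by 2.14 times the difference between the groups. Less attached fat and an effect of Fgf17 on these cells stay open and were not tested, because tissue taken along at dissection and cells within the heart carry the same transcripts.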

How the results depend on the processing

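The alternatives that leave out control libraries 2 and 3, count control libraries 1 and 4 as 1 sample or rescale without mitochondrial genes were chosen after seeing the data. Over 87 named genes other than Fgf17, 1797 of 1880 values kept their direction and their side of the threshold, 4 passed it and 79 changed sign. Fgf17 kept its direction throughout, and the white adipocyte list stayed past the threshold in every alternative except the estimated correlation and fry. The cause of each change below was not tested unless said. The planned count test was not run because no counts were used here, and no depth sets a limit on single genes. The minimum mean of 0.1 kept every gene that no filter kept.

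Log2 changes here are as fitted. Genes past limma's threshold numbered 4 higher and 1 lower with array quality weights (Fgf17 log2 change 3.44) and 5 and 1 without control libraries 2 and 3 (3.34). The latter calls rest on control libraries 1 and 4 as the only controls. Counting these as 1 sample leaves 1 control sample, and Fgf17 stayed at 3.34. With 1 library left out, genes past the threshold ranged from 0 to 1 higher and 0 to 3 lower, with Fgf17 between 4.05 and 4.99. The single calls were Atxn7, U2af1l4 and Azin1 lower without control library 1, Mapt higher without control library 2, Tmem168 higher and Slco2b1 lower without control library 3, and Krcc1 lower without AAV-FGF17 library 3. Krcc1 stood at 56.9 FPKM in that library, among the controls at 53.6 to 58.85, and between 9.79 and 11.5 in the other AAV-FGF17 libraries. The gene overlaps another on its strand.

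The replicate number was also fitted as a block. Same-number libraries correlated between -0.109 and 0.022 in their deviations, and 0 libraries correlated best with their own number. The values thus showed no pairing by number, but a weaker pairing cannot be excluded and the labels leave it unstated. With the block the limma adjusted p of Fgf17 was 0.0730, against 0.248 without it. The block gave 0 genes in each direction, and it moved the fetal and hypertrophic list past the threshold (camera adjusted p = 0.0153), with the brown adipocyte list at 0.04995 and the neutrophil list at 0.0153.

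Camera calls changed as follows, as adjusted p. With no filter or a minimum mean of 0.1, the basement membrane list stood at 0.0513 and brown adipocyte at 0.0463. The platelet list, too small in the main fit, passed as higher. With a minimum of 5 FPKM, 4 lists passed, and glycolysis stood at 0.0526, basement membrane at 0.163, lipid synthesis at 0.130 and smooth muscle at 0.0504, while the mesothelial list had too few members left. After median-of-ratios scaling the 35 markers of the fat, atrial, smooth muscle and mesothelial lists together had a median log2 change as fitted of -0.52. Brown adipocyte markers passed at 0.0398 with median-of-ratios scaling. The fetal and hypertrophic list passed at 0.0406 with that scaling, 0.0448 with quantile normalization and 0.0244 after rescaling without mitochondrial genes, where 14 lists passed, among them adult sarcomere at 0.0322, fibrillar collagen at 0.0402, brown adipocyte at 0.0283 and cardiomyocyte at 0.0442. Quantile normalization put the mitochondrial list at 0.187. Array weights put glycolysis and lipid synthesis at 0.194 and basement membrane at 0.420, with ribosomal protein genes higher at 0.000186 and cell cycle genes higher at 0.0414. Without control libraries 2 and 3, the mitochondrial list stood at 0.292, glycolysis at 0.756, basement membrane at 0.505 and lipid synthesis at 0.229, and with control libraries 1 and 4 counted as 1 in addition, at 0.339, 0.760, 0.510 and 0.209. Ribosomal protein genes were higher at 3.19e-11 without control libraries 2 and 3, and nuclear-encoded respiratory chain genes turned from lower to higher at 8.09e-05. The values listed for these lists with control libraries 1 and 4 counted as 1 in addition are 8.18e-10 and 0.000454. Leaving out control libraries 2 and 3 and also counting 1 and 4 as 1 leaves 1 control sample. The adjusted p-values listed for that setting are therefore no test, and no call is drawn from them. Counting control libraries 1 and 4 as 1 alone left 4 lists, with atrial and erythroid at 0.0562, smooth muscle at 0.0657, and mesothelial and lipid synthesis at 0.0601. The estimated correlation left 0 lists, at 0.974 for the mitochondrial, smooth muscle, erythroid, white adipocyte and mesothelial lists and 0.981 for glycolysis, basement membrane, lipid synthesis and atrial lists. Fry left 0 as well, at 0.439 for the erythroid list and 0.319 for the other 8.

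With 1 library left out, 4 to 15 lists passed. Tricarboxylic acid cycle, angiogenic and platelet lists, not described here, passed in 1 case each. Adjusted p ran from 0.0104 to 0.0699 for glycolysis, 0.0108 to 0.1101 for basement membrane, 0.0108 to 0.113 for lipid synthesis, 0.0128 to 0.358 for ERK feedback, 0.0128 to 0.601 for glucocorticoid response, 0.0410 to 0.357 for FGF ligands, 0.0194 to 0.406 for fetal and hypertrophic, 0.0429 to 0.434 for adult sarcomere, 0.0389 to 0.576 for fibrillar collagen, 0.0279 to 0.131 for brown adipocyte, 0.0382 to 0.222 for endothelial, 0.0291 to 0.895 for macrophage, 0.0039 to 0.969 for ribosomal protein, 9.58e-06 to 0.0621 for atrial, 0.000115 to 0.0668 for smooth muscle, 6.59e-06 to 0.0609 for erythroid and 0.000543 to 0.079 for mesothelial lists.

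Genes that changed sign, none of them past the threshold, are given as log2 changes as fitted. With median-of-ratios scaling, Fgf1 stood at 0.0040, Lyve1 at 0.028, Ebf1 at 0.061, Cpa3 at 0.014, Acta1 at 0.11, Eif2s3y at 0.049 and Ddx3y at 0.089. With quantile normalization, Lyve1 stood at 0.018, Ebf1 at 0.073, Cpa3 at 0.029, Cox8b at 0.061, S100b at 0.020, Acta1 at 0.11, Eif2s3y at 0.038 and Ddx3y at 0.080. With array weights, Fgfbp3 stood at 0.23, Fabp3 at 0.067, Gsn at 0.089, Cox8b at 0.019, S100b at 0.20, Ckm at 0.0025, Acta1 at 0.25 and Ddx3y at 0.025. Without control libraries 2 and 3, Fgfbp3 stood at 0.35, Mb at 0.082, Fabp3 at 0.20, Gsn at 0.10, Lyz2 at 0.031, Cox8b at 0.10, S100b at 0.17, Ckm at 0.095, Acta1 at 0.57 and Ddx3y at 0.0037. With control libraries 1 and 4 counted as 1, Lyve1 stood at 0.013, Hbb-bs at -0.014 and Cpa3 at 0.057. With both of these changes, Fgfbp3 stood at 0.34, Mb at 0.082, Fabp3 at 0.20, Gsn at 0.10, Lyz2 at 0.029, Cox8b at 0.10, S100b at 0.16, Ckm at 0.095, Acta1 at 0.57 and Ddx3y at 0.0035. After rescaling without mitochondrial genes, Fgf1 stood at 0.056, Fgfr1 at 0.0088, Lyve1 at 0.077, Lyz2 at 0.037, Ebf1 at 0.10, Cpa3 at 0.041, Cox8b at 0.048, S100b at 0.031, Acta1 at 0.16, Eif2s3y at 0.10 and Ddx3y at 0.14. With 1 library left out, Flrt2 ranged from -0.29 to 0.10, Acta1 from -0.65 to 0.33, Cpa3 from -0.22 to 0.089, Fgfbp3 from -0.36 to 0.20, C1qb from -0.0016 to 0.25, Lyve1 from -0.25 to 0.014, Hbb-bs from -0.018 to 0.42, Pf4 from -0.079 to 0.41, Ebf1 from -0.14 to 0.0083, Gsn from -0.39 to 0.012 and S100b from -0.24 to 0.12.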

Other observations

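The tests of transcript number and gene overlap and the comparisons with other splits were set before their results were seen, while the genes at 2 levels were picked from the values and the bootstrap interval and the reduction to 25 genes were added once the first results were known. The lists without control libraries 2 and 3 were tested after the data were seen. Nqo1, a quinone reductase of the NRF2 and antioxidant list, was the only tested member of that list past limma adjusted over the list alone, at 13.5 ± 1.35 FPKM in AAV-FGF17 hearts and 9.16 ± 0.993 in controls. The list as a whole did not pass (camera adjusted p = 0.314). Pi16, a marker of adventitial fibroblasts, passed adjusted over the fibroblast list alone, at 7.28 ± 2.22 against 15.3 ± 4.94 FPKM, while the fibroblast list did not pass (camera adjusted p = 0.356). The endothelial list did not pass either (camera adjusted p = 0.093), with Cdh5, VE-cadherin, at 43.6 ± 5.26 against 56.0 ± 8.31 FPKM. Macrophage markers did not pass (camera adjusted p = 0.314), with Lyz2 at 97.1 ± 25.5 against 107 ± 23.2 FPKM and C1qb at 42.8 ± 10.4 against 39.2 ± 4.62. The pericyte gene Rgs5 measured 150 ± 12.9 against 137 ± 8.89 FPKM. Without control libraries 2 and 3, cytosolic ribosomal protein genes and nuclear-encoded respiratory chain genes were higher as lists (camera adjusted p = 3.19e-11 and 8.09e-05, each 0.963 with an estimated correlation). Their median changes as fitted were 0.12 and 0.06. Only control libraries 1 and 4, the most similar pair, were left as controls. Respiratory chain scores of AAV-FGF17 libraries 1 and 3, -0.140 and -0.131, lay between those of control libraries 1 and 4, -0.0719 and -0.144. AAV-FGF17 libraries 2 and 4 scored above both, at 0.0529 and 0.0920. Ribosomal protein scores of all 4 AAV-FGF17 libraries, the lowest -0.0805, lay above those of control libraries 1 and 4, -0.120 and -0.172.

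The 6 genes past the limma threshold without control libraries 2 and 3 were Selenof, Mapt, Fgf17, Tmem168, Lactb and Amigo1, named after their values were seen. Their calls rest on control libraries 1 and 4, the only controls left and the most similar pair, counted as 2 samples. Counting these as 1 leaves 1 control sample, and the Fgf17 log2 change as fitted stayed at 3.34. Selenof stood at 7.88 and 7.56 FPKM in control libraries 1 and 4 and at 16.2 and 12.4 in control libraries 2 and 3. In AAV-FGF17 hearts it lay between 16.6 and 19.5 FPKM. Lactb stood at 10.6 and 10.7 FPKM in control libraries 1 and 4, at 25.9 and 18.1 in the other controls and between 18.1 and 19.4 in AAV-FGF17 hearts.

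Of the 35 ways to part the 8 libraries into 4 and 4, 35 gave at least as many higher genes and 35 at least as many lower genes as the real one, which gave 0 in each direction, and the highest of the others gave 2 genes. With 0 genes every split must reach as many, so these 2 counts decide nothing. For the 936 genes at an unadjusted p under 0.05, 8 of the 35 splits gave as many, with 1234 as the highest of the others, and all 8 kept control libraries 2 and 3 on the same side. For the 9 lists past camera, 12 of the 35 splits gave as many and the highest of the others gave 18. Chance therefore could not be excluded for the genes at an unadjusted p under 0.05 or for the lists.

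Some genes stood at 2 levels that did not follow the groups. Over 4778 nuclear genes with a mean of at least 5 FPKM, 45 had a gap of at least 1 log2 unit between 2 sets of libraries, each set narrower than the gap. Of these, 9 parted control libraries 2 and 3 from the rest and 11 had the low libraries of the atrial or fat patterns, among them Myl4, Sln, Pck1 and Scd1, which left 25. Rac1 stood at 38.4 FPKM in AAV-FGF17 library 3 and at 42.6, 35.4 and 39.0 in control libraries 2 to 4, but between 7.84 and 9.19 in the other 4 libraries. Whether reads divided among genes or transcripts may cause such steps stays open: the odds ratio of overlapping another gene on the strand was 2.12 in the 25 (Fisher's exact p = 0.148) and 1.39 in all 45 (p = 0.418), and the ratio of median annotated transcripts to that of the other genes was 1 in both (bootstrap 95% intervals 0.8 to 1.6 and 0.6 to 1.2).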
